A study of Mus musculus with 6 samples.

How the data were processed

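RNA was sequenced from satellite cells, the stem cells of skeletal muscle, of mice at 4 months of age. Per the labels' protocols, hindlimb muscle was digested with collagenase, cells positive for the surface proteoglycan Sdc4 were sorted, and RNA was isolated with Trizol. The labels give 6 samples, 3 wild-type and 3 AUF1-null. Per the submitters' processing notes, TopHat2 2.0.9 and Cufflinks 2.2.1 were used. The annotation, the library normalization method and the strand setting are not given in the sources used here. The notes name the mm9 build, but the gene positions in the table are those of GRCm38 (mm10). Of 21358 genes matched by symbol and chromosome to the RefSeq annotation of GRCm38, 99.5% overlapped the annotated gene, and 36 genes lay on scaffolds that carry GRCm38 names. Positions are therefore given in GRCm38 and 1-based, with 1 added to the start column.

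The analysis used 1 table with the column layout of Cuffdiff, which compares 2 conditions gene by gene. Per the file headers, the authors deposited 1 value per gene for each condition, which Cuffdiff writes on the FPKM scale after pooling the replicates. The headings themselves name no unit. The authors also deposited the log2 fold change of the second condition over the first, a test statistic that is used here as a score only, and a p-value with its q-value. The table names its conditions q1 and q2, and no label used here says which of them is AUF1-null. The name under which the table was deposited puts wild type before knockout, and Cuffdiff numbers conditions in the order in which they are given to it, but the table does not state that order. No genotype was assigned from values, order or names, and every direction is given as q2 relative to q1. The table holds 23361 genes, of which 14858 have the status OK and count as tested. Another 8499 were not tested by the authors (status NOTEST) and 4 had too many fragments for the authors' software (status HIDATA). The log2 fold change equalled that of the group values within 0.001 for all tested genes with both sides above 0 except Atxn7l1 and Syne1. The deposited q-value equalled a Benjamini-Hochberg adjustment of the deposited p-value over the tested genes. The smallest p-value in the table is 5e-05, shared by 69 genes, and the smallest q-value is 0.0108. In the gene column, 27 names had been turned into dates, and 99 lines name several genes together; neither kind was used as a named gene.

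Values per sample were not analysed here, so no SD, standard error or n stands beside a gene, and no test between samples was run. The labels do not say whether samples of a group came from separate mice, so any spread between samples behind the authors' p-values may be technical. How much of that spread each p-value reflects was not examined here. A gene was called when its status was OK and the deposited q-value was below 0.05. The test, the gene lists, the rule for named genes and most other settings tried were fixed before the data were examined. The rule named Hnrnpd, the 10 called genes with the largest rise and the 10 with the largest fall among genes above 0 on both sides and at least 1 FPKM on the higher side, without predicted genes. It also named Mmp9, Twist1, Pax7, Myod1, Myf5, Myog, Sdc4, Cdkn1a and Ccnd1. From each list it took up to 4 called genes or, where none was called, the 2 with the highest mean. Other genes named in the text were chosen after their values were seen.

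For each of 29 fixed gene lists, the called members were compared with all other tested genes by Fisher's exact test, two-sided, for each direction, with Benjamini-Hochberg adjustment over the 58 tests. The median log2 fold change of each list was placed among 10000 random lists of the same size, matched on mean value in 20 bins. Genes with 1 side at 0 have no finite log2 fold change and were left out of these medians. Lists for cartilage, marrow precursors and eosinophils were added after the called genes were known. Called genes within 10 Mb of Hnrnpd were compared with called genes elsewhere by Fisher's exact test. The longest annotated 3' UTR of each gene was taken from protein-coding transcripts of GENCODE vM21, which 92.6% of tested genes and 97.3% of genes called higher had. The presence of WTATTTAW, where W is A or T, was tested by 10000 permutations within 10 bins of 3' UTR length, two-sided. Genes are not independent replicates in any of these tests over genes. Alternatives covered the q threshold, low values, a minimum fold, pseudocounts of 0.1 and 1, centring, the window size and the motif. Calls without genes at exactly 0, lists without the members of the neutrophil list, and the unadjusted p near Hnrnpd, were added after the data were seen.

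The tests over genes were tested on simulated data. Among 200 draws of lists of 30 genes from 14779 genes, a log2 shift of 1 placed 100% of lists above the central 95% of random lists. Of unshifted lists, 4% fell outside it. Values were drawn independently for each gene, so this rate does not cover lists whose members move together. Fisher's exact test found 100% of lists given 5 extra called genes. The motif test was run on 13045 genes. It found a log2 shift of 0.2 in 100% of 40 draws, with a median estimate of 0.20. With a trend of 0.05 per doubling of 3' UTR length and no shift, it passed 0.05 in 12.5% of these 40 draws. A larger run of 300 draws was added because of that rate and gave 5.33% with the trend and 4.67% without it; both runs together gave 6.18% of 340 draws.

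Depth per sample is not given in the sources used here. Low values of single-exon receptor genes of 850 to 1100 bases fell on repeated steps, a check chosen after the values were seen. Each step was shared by 3 genes; 2 steps lay in q1 and 1 in q2. If a step were 1 fragment in 1 of 3 equally weighted libraries, those libraries would hold about 20700000 and 18400000 fragments in q1 and 16900000 in q2. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.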

Results

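Satellite cells sorted on Sdc4 from the hindlimb muscle of mice aged 4 months were profiled by RNA sequencing in 3 wild-type and 3 AUF1-null samples. AUF1, the product of Hnrnpd, binds AU-rich elements in the 3' UTRs of mRNAs and affects their stability. The comparison asks which transcripts differ between cells sorted as satellite cells from both genotypes. The authors' deposited table holds 1 value per condition on the FPKM scale, pooled over replicates, so there is no replicate spread beside a value. The conditions are named q1 and q2 in that table, and which of them is AUF1-null is not given in the sources used here, so directions below are those of q2 relative to q1 and not of a genotype.

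Hnrnpd, at chr5:99955936-99978938 (GRCm38), was listed at 7.5 in q1 and 5.59 in q2 in the authors' deposited table. Its log2 fold change there was -0.42 (Cuffdiff p = 0.291, q = 0.999 in the authors' deposited table), so the targeted gene did not pass the test. The part of the gene that was deleted is not given in the sources used here, and transcripts from the rest of the locus can still be counted. Hnrnpd therefore does not tell which condition is AUF1-null.

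Genes of neutrophils were among those with the largest rises in q2. S100a8 and S100a9, which form calprotectin in neutrophils, rose from 426 to 6478 and from 222 to 3185 in the authors' deposited table. Il10, an anti-inflammatory cytokine, rose 21.0-fold from 0.45 to 9.43 in the authors' deposited table, although its q of 0.0490 lay close to the threshold; with a pseudocount of 1 the rise was 7.2-fold, below the 15.2-fold of S100a8. The collagenase gene Mmp8 rose 12.5-fold, the antimicrobial peptide gene Camp 12.4-fold, Ly6c2 11.3-fold, Chi3l3 11.3-fold, Retnlg 11.3-fold and Slpi 11.2-fold, and Igj, the joining chain of antibodies, went from 4.93 to 54.2, all by the authors' deposited table. Reads of Ly6c2 can be shared with its near copy Ly6c1, so its level is uncertain.

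Fewer genes fell in q2, among them the collagen genes Col2a1 and Col11a1 and the endothelial gene Plvap. Col2a1, the main collagen of cartilage, fell from 1.69 to 0.05 and Col11a1 from 5.27 to 0.87 in the authors' deposited table. The 31.5-fold difference of Col2a1 rests on a value near 0 and was 2.55-fold with a pseudocount of 1. Plvap, a protein of endothelial diaphragms, fell from 139.6 to 28.8 in the authors' deposited table, and Hal, the enzyme that starts histidine breakdown, from 93.4 to 13.5. The kinase gene Nuak1 fell from 22.3 to 3.73, Nxpe4 from 20.3 to 4.75, the interferon-induced GTPase gene Gbp1 from 96.6 to 24.8, Zer1 from 10.2 to 3.26 and the receptor gene Ret from 5.14 to 1.68, again by the authors' deposited table. Erdr1 was listed at 85.7 and 19.7 with q = 0.0201 in the authors' deposited table, but it lies in a region with near-identical copies and is uncertain.

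In all, 91 of 14858 tested genes were called at the authors' Cuffdiff q below 0.05, 74 of them higher and 17 lower in q2. Of these, 63 and 10 were above 0 on both sides. The rises above 0 ranged from 2.5 to 21.0-fold with a median of 6.47, and the falls from 3.07 to 31.5-fold with a median of 4.60. At an unadjusted p below 0.05 there were 890 genes, 553 higher and 337 lower, where 742.9 would be expected by chance. The other 18 calls had a side listed at exactly 0, among them Ifng at 1.34 and Il17a at 1.07 in q2 and Acan at 0.47 and Clec3a at 1.13 in q1 by the authors' deposited table; no fold is given for them. Without these, 10 genes remain called lower. With at least 1 FPKM on the higher side and the p-values adjusted again, Il10, Adam8, Cytip and Col2a1 were no longer called, at a q of 0.0510 each, although all are above that minimum. No gene was called at a q below 0.01, since the smallest q in the table is 0.0108.

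**Figure D1:**
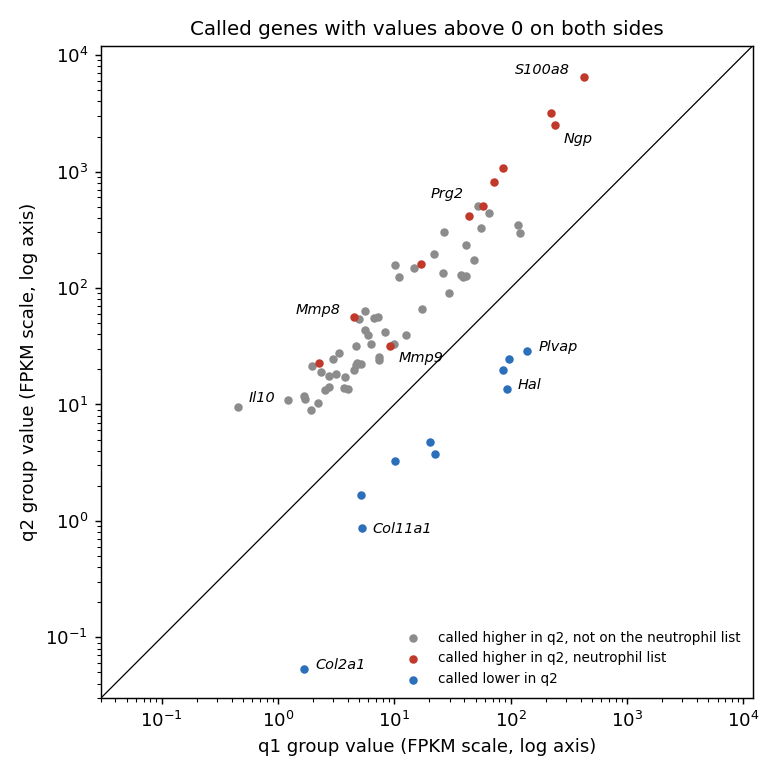
Group values of the 73 called genes above 0 on both sides, q1 on the horizontal and q2 on the vertical axis, both log axes on the FPKM scale; each point is 1 gene and the line marks equal values. Neutrophil list members in red lie above the line, with S100a8 at 426 in q1 and 6478 in q2, and the 10 genes called lower, in blue, lie below it.

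Neutrophil markers formed the list with the most called genes. Of 16 tested members, 11 rose and the other 5 lay above 0 without passing the test. Besides those already named, Ngp rose from 241 to 2537, Ltf, which codes for lactoferrin, from 43.8 to 418, Mpo, the myeloperoxidase of granules, from 16.8 to 159.6 and Lcn2 from 57.7 to 502 in the authors' deposited table. Elane, at 18.9 and 255 in the authors' deposited table, did not pass (q = 0.999), and it shares the position chr10:79697305-80369637 with Prtn3 there. Among receptor genes, Fpr1 rose from 2.26 to 22.9, while Fpr2, Csf3r and Cxcr2 did not pass, with log2 fold changes of 2.32, 1.28 and 0.42 in the authors' deposited table. The list was enriched among called genes (adjusted p = 5.34e-21, Fisher's exact test), with 14 members higher when adjusted over the list alone. Its median log2 fold change was 3.30.

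Few macrophage, lymphocyte and erythroid markers were called, and none of these 3 lists was enriched, although the medians of all 3 lay above the central 95% of random lists. Among 22 tested macrophage and monocyte markers, Ccr2 rose from 7.41 to 25.4 and Tyrobp, a signalling adaptor of myeloid cells, from 115 to 347 in the authors' deposited table; 18 members lay above 0, 4 lay below 0, among them Csf1r at 83.8 and 49.7, and 10 passed when adjusted over the list alone. The list itself was not enriched among called genes (adjusted p = 0.0615, Fisher's exact test), although its median log2 fold change of 0.83 lay above the random lists (-0.13 to 0.18). All 17 tested lymphocyte markers lay above 0, with a median log2 fold change of 2.01, or 1.12 with a pseudocount of 1 (random lists -0.35 to 0.34), since most were low, and Nkg7 alone rose, from 3.37 to 27.6 in the authors' deposited table; 5 passed when adjusted over the list alone (enrichment adjusted p = 0.675, Fisher's exact test). The 7 tested erythroid markers had a median of 0.93 (random lists -0.36 to 0.43) with none called (enrichment adjusted p = 1, Fisher's exact test), and Hba-a2 was listed at 429.9 and 496 and Hbb-b2 at 224 and 347 in the authors' deposited table, where near-identical globin copies make single values uncertain.

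Matrix metalloproteinases, cytokines and mRNAs described as AUF1 targets also held more called genes than other tested genes. Of 32 metalloproteinase and inhibitor genes, Mmp8, Mmp9, Adam8 and Plaur rose; Mmp9, a gelatinase, went from 9.16 to 32.0, Adam8 from 7.45 to 24.3 and Plaur, the urokinase receptor, from 119 to 298 in the authors' deposited table. The list was enriched (adjusted p = 0.000355, Fisher's exact test; 5 higher when adjusted over the list alone), but its median log2 fold change was -0.06, and without Mmp8 and Mmp9, which are also neutrophil markers, the enrichment was lost (adjusted p = 0.0940, Fisher's exact test, chosen after seeing the data). Of 27 tested AUF1 targets, Mmp9, Il1b, Il10 and Plaur rose (adjusted p = 0.000265, Fisher's exact test), with 6 higher and 2 lower when adjusted over the list alone. With 17 members above and 10 below 0, the median of 0.11 lay inside the random lists (-0.13 to 0.18), so no shift of the list as a set was detected. Without Mmp9 the AUF1 target list stayed enriched (adjusted p = 0.00824, Fisher's exact test, also chosen after seeing the data). That list was drawn from knowledge of the literature, which can include work on these samples, so its count is not independent evidence. Among 39 cytokines and chemokines, Il10, Il1b and Ccl8 rose (adjusted p = 0.0138, Fisher's exact test; 8 higher when adjusted over the list alone; median 0.29, random lists -0.12 to 0.15). Ccl8, a chemokine for monocytes, went from 65.3 to 442 and Il1b from 39.3 to 125 in the authors' deposited table. With at least 1 FPKM and p-values adjusted again, Il10 lost its call and the cytokine list was no longer enriched (adjusted p = 0.130, Fisher's exact test).

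Interferon response genes Oasl1 and Irf7 rose, from 3.76 to 17.1 and from 41.4 to 127 in the authors' deposited table. With 2 of 27 tested members called, also 2 when adjusted over the list alone, the list was not enriched (adjusted p = 0.0766, Fisher's exact test; median 0.26, random lists -0.13 to 0.16). Among 29 tested cell cycle genes, Ccnb2, a cyclin of mitosis, rose from 2.72 to 14.1 in the authors' deposited table, 26 lay above 0, and 7 were higher and 1 lower when adjusted over the list alone (enrichment adjusted p = 0.978, Fisher's exact test; median 0.82, random lists -0.22 to 0.16). Top2a was listed at 3.59 and 9.97 and Ccnd1 at 25.7 and 11.2 without passing (q = 0.109 and 0.187 in the authors' deposited table).

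The genes that define satellite cells were not called, but Pax7 among them was low in both conditions. None of 23 tested satellite cell identity genes or 19 myogenic genes passed, over all genes or when adjusted over the list alone, with medians of -0.13 and -0.10; by Cuffdiff's unadjusted p, 1 and 2 of them lay below 0.05. Pax7, the transcription factor of satellite cells, was listed at 1.16 and 0.85, Myf5 at 16.7 and 17.8, Myod1 at 0.63 and 0.88, Myog at 0.94 and 0.31 and the sorting marker Sdc4 at 173 and 270 in the authors' deposited table. Pax7, Myod1 and Myog were low, and even a Myog value 3.05-fold lower in q2 was not called. The lack of a call therefore does not show that these genes were unchanged. Cav1 was at 1266 and 1156, Cd34 at 259.5 and 219, Cryab at 150.3 and 158 and Igfbp5 at 120.3 and 78.6 in the authors' deposited table. Endothelial genes were also abundant in both conditions: Fabp4 was at 14386 and 12032, Ly6c1 at 1561 and 1422, Egfl7 at 911 and 822 and Pecam1 at 421 and 327 in the authors' deposited table. Whether the values of Cav1 and Cd34 came from satellite cells or from endothelial cells was not tested. Some markers of other cell types were high as well. In the authors' deposited table, Gsn of fibroblasts was at 3583 and 2822 and Rgs5 of pericytes at 2279 and 3553. Mbp of Schwann cells was at 595 and 651 there. The share of satellite cells among the sorted cells was not assessed here, so differences cannot be assigned to satellite cells alone. Twist1, at 2.86 and 0.80, and Cdkn1a, at 238 and 315, did not pass (q = 0.485 and 0.999 in the authors' deposited table).

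Several lists lay to 1 side as sets without a called member; the called genes Plvap, Col2a1 and Col11a1 are not on the endothelial and matrix lists. All 28 tested contractile genes were above 0, with a median of 0.75 against -0.13 to 0.17 in random lists; Acta1, skeletal actin, was at 723 and 1262 and Tnnc2 at 517 and 1101 in the authors' deposited table, and 1 member passed when adjusted over the list alone. Of 33 extracellular matrix genes, 31 were below 0 (median -0.45, random lists -0.13 to 0.14), as were 21 of 22 endothelial genes (median -0.31, random lists -0.10 to 0.19) and all 9 tenocyte genes (median -0.66, random lists -0.29 to 0.33). Sparc was at 2007 and 1583, Bgn at 240.2 and 223, Fmod at 203 and 175 and Thbs4 at 94.8 and 51.3 in the authors' deposited table. No member of the matrix and endothelial lists passed when adjusted over the list alone, and 1 tenocyte gene did; by Cuffdiff's unadjusted p, 7 contractile, 5 matrix, 4 endothelial and 3 tenocyte genes lay below 0.05. Of the 29 lists, 10 had medians above and 6 below the central 95% of random lists. The 1.45 expected by chance holds only for lists of unrelated genes. Members of 1 list can move together, so the count cannot be weighed against that number.

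**Figure D2:**
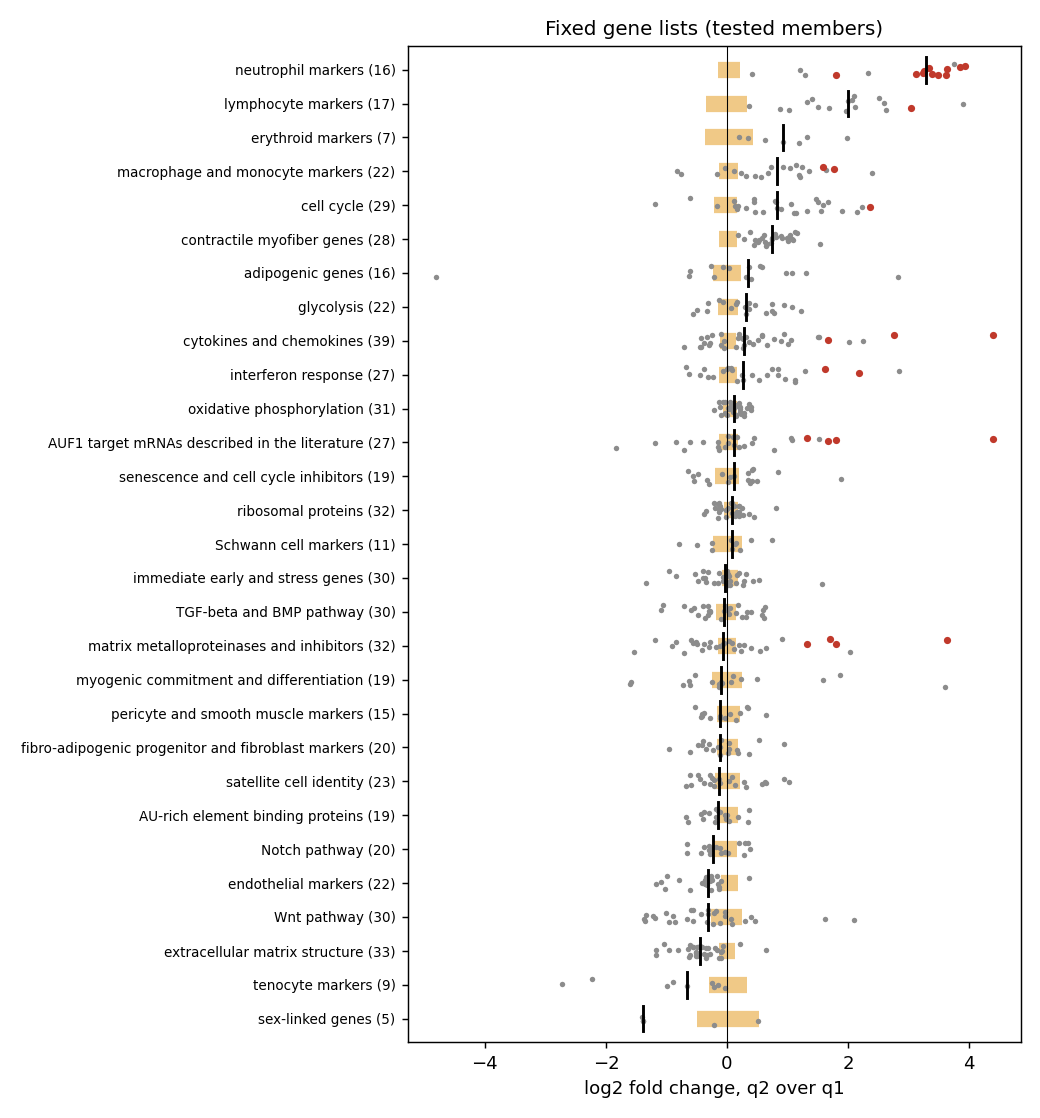
Log2 fold change of q2 over q1 for the tested members of each of the 29 fixed lists with a finite value, with the number tested in brackets; grey points are genes not called, red points called genes, black bars the list medians and orange bands the central 95% of 10000 matched random lists. Neutrophil markers have the highest median, 3.30, and contractile genes lie together to the right of 0 with a median of 0.75.

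Among the remaining lists, the medians of adipogenic genes (0.34), glycolysis (0.31), the Wnt pathway (-0.32), the Notch pathway (-0.23) and sex-linked genes (-1.39, or -0.68 with a pseudocount of 1) lay outside the central 95% of random lists. Cd36 was at 1484 and 1518, Aldoa at 811 and 1043, Ldha at 383 and 469, Ctnnb1 at 153 and 135, Sfrp4 at 66.0 and 56.0, Dll4 at 57.6 and 70.9 and Hes1 at 60.0 and 56.3 in the authors' deposited table. Y-linked Ddx3y was at 29.6 and 11.3 and Eif2s3y at 24.1 and 20.8 in the authors' deposited table. Xist, which silences an X chromosome in females, was at 5.44 and 7.77 there. Xist and Y-linked transcripts were therefore present in both conditions. Of 5 tested sex-linked genes, 1 lay above 0 and 4 below, and whether the mix of sexes differed between conditions was not tested. Medians inside that range were found for fibro-adipogenic and fibroblast markers (-0.11), pericyte and smooth muscle markers (-0.11), Schwann cell markers (0.08), senescence genes (0.11), AU-rich element binding proteins (-0.15), immediate early genes (-0.03), the TGF-beta and BMP pathway (-0.05), oxidative phosphorylation (0.12) and ribosomal proteins (0.09). None of these 14 lists held a called gene, and when adjusted over the list alone only 1 senescence gene passed. Gsn was at 3583 and 2822, Dcn at 1259 and 1407, Rgs5 at 2279 and 3553, Tagln at 544 and 405, Mbp at 595 and 651, Pmp22 at 613 and 647 and Igfbp7 at 187 and 134 in the authors' deposited table. Zfp36 was at 4229 and 4325, Rbm3 at 212 and 272, Hspa8 at 4424 and 5376, Id3 at 915 and 930.3, Id1 at 238 and 299.97, Cox4i1 at 773 and 734, Cox6c at 435 and 449.9, Rpl32 at 1538 and 1768 and Rpl13 at 1608 and 1675 in the authors' deposited table.

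Mice were bred through a C57BL/6 strain of mixed background, so genes flanking Hnrnpd on chromosome 5 were compared with genes elsewhere. None of 113 tested genes within 10 Mb of Hnrnpd was called at the authors' Cuffdiff q, against 91 of 14744 elsewhere, or 0.617% (p = 1, Fisher's exact test, two-sided). By Cuffdiff's unadjusted p below 0.05, a threshold added after the data were seen, the share near Hnrnpd was the higher one, 15 of 113 genes or 13.3% against 5.93% elsewhere (p = 0.00391, Fisher's exact test). Of these 15 genes, 6 were higher and 9 lower in q2, and none passed the adjustment. They included the neighbouring chemokine genes Cxcl1, at 462 and 790, and Cxcl2, at 89.9 and 257, and the guanylate-binding protein genes Gbp4, at 64.3 and 26.6, and Gbp6, at 19.2 and 7.01, in the authors' deposited table. The nearest called genes on this chromosome were Igj at chr5:88519809-88527897 and Oasl1 at chr5:114923240-114937911 (GRCm38), which the window of 20 Mb includes, with 2 of 232 genes called there.

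No difference was detected between transcripts with the AU-rich motif WTATTTAW in the 3' UTR and transcripts of the same 3' UTR length without it. Over 4438 genes with and 9286 without the motif, the length-matched difference in median log2 fold change was -0.0075 (permutation p = 0.467, two-sided). Medians without length matching were -0.06 with and 0.01 without the motif. Of the 72 genes called higher that have an annotated 3' UTR, 15 carried the motif, or 20.8%, against 32.4% of other tested genes (p = 0.0425, Fisher's exact test). Their 3' UTRs were shorter, with a median of 478 bases against 1142, and length-matched draws gave 18.4% with a central 95% from 11.1% to 26.4%.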

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

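Transcripts of 3 genes stood out in values that the comparison does not use. Malat1 was listed at 0 in q1 and 1610 in q2, Ubb at 0 and 1921 and Gm1821 at 0 and 1095 in the authors' deposited table. All carry the status HIDATA, which Cuffdiff gives where a locus holds too many fragments to be quantified. Under that status a value of 0 is not a measured absence, and no fold is given. What the values would be without that status was not tested.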

How the results depend on the processing

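Leaving out genes at exactly 0, removing neutrophil list members from other lists and the unadjusted p near Hnrnpd were chosen after seeing the data; the other alternatives were planned. At a q below 0.01 there were 0 called genes, 0 higher and 0 lower, with 0 enriched lists and 0 neutrophil markers, because the smallest q in the table is 0.0108. At a q below 0.10 there were 110 calls. Genes called lower numbered 11 instead of 17 with at least 1 FPKM on the higher side and p-values adjusted again, where 5 were under the minimum and Col2a1 lost its call on adjustment, and 10 without genes at 0. Other counts of called genes under these settings, adjustment over all genes and a minimum of 2-fold stayed within 1.5 times, with 73 to 110 calls in all. Pseudocounts and centring cannot change calls that rest on the deposited q, so their 91 calls say nothing about stability. Enriched lists numbered 3 or 4 apart from the q of 0.01. The share called near Hnrnpd went from below to above that elsewhere with 20 Mb, 0.862% against 0.609% (p = 0.655, Fisher's exact test), and with an unadjusted p below 0.05, to 13.3% within 10 Mb (p = 0.00391), 11.9% within 5 Mb (p = 0.104) and 11.2% within 20 Mb (p = 0.00191, all Fisher's exact test); the cause was not tested, and a q of 0.01 gives no share. Pseudocounts cannot turn a gene's direction and centring moves it by only 0.019, so the kept direction of Hnrnpd (log2 -0.42 to -0.37) and of all 78 named genes is no evidence of stability either. The motif difference stayed below 0 without passing 0.05 (-0.0214 to -0.0027). Of 87 list medians 5 moved: with a pseudocount of 1 neutrophil markers had 3.20, lymphocyte markers 1.12, erythroid markers 0.63, cell cycle genes 0.60 and sex-linked genes -0.68. No paired analysis was possible because the table holds 1 value per condition. For that reason edgeR and DESeq2 normalization, leaving out each replicate, a replicate block and other splits of the samples were not run, and 1 sample may decide a call unseen. Depth per sample is unknown, so low values carry no limit of detection.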

Other observations

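The tests of granulocyte share, library scaling, cartilage, exact zeros, members without the motif and unadjusted p-values near Hnrnpd were chosen after the results they bear on were seen; the tests of AU-rich motifs in called genes and of marrow precursors were written before their values were looked at, though the called genes were known by then.

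Eosinophil genes, a list added after the called genes were seen, stood with the neutrophil genes. Of 7 tested members, Prg2, the major basic protein of eosinophil granules, rose from 52.0 to 509.9 and Epx, their peroxidase, from 2.73 to 17.4 in the authors' deposited table. The median log2 fold change was 2.39, with random lists from -0.44 to 0.46, and 6 of 7 members lay above 0 (enrichment unadjusted p = 0.000506, Fisher's exact test). Both called members belonged to the genes from which the list was thought of, so they are not independent of it.

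Genes near Hnrnpd had more low unadjusted p-values than genes elsewhere, a comparison made after the data were seen. The share of 13.3% within 10 Mb was reached by 0.261% of 13798 windows of the same size around other tested genes, which had a median of 5.75% and a central 95% reaching up to 11.4%. These windows overlap and neighbouring family members such as Gbp4, Gbp6 and Gbp10 can share reads, so neither they nor the genes are independent.

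Granulocyte genes were higher in q2 as a set. A shift in the authors' library scaling is argued against by the median of all expressed genes, which was -0.019 in log2. Stabilisation through WTATTTAW is argued against only for the 13 of 16 neutrophil genes whose annotated 3' UTR lacks it. Their median of 3.40 (random lists -0.16 to 0.23) largely restates that of the list, so only the count without the motif is new. Binding of AUF1 to other sequences was not tested. For called genes at large the motif share was 1.13 times the length-matched share, inside the central range of draws, so stabilisation cannot be told apart from chance for genes with the motif. A larger share of granulocytes among the q2 cells stays open, since the neutrophil list median of 3.30 restates the pattern. Some members, Cxcr2 at 0.42 and Csf3r at 1.28 among them, moved less. This unevenness does not argue against a larger share, since members need not all come from the same kind of granulocyte. The kind of granulocyte was not tested. S100a8 was at 6478 and Ngp at 2537 in q2 by the authors' deposited table. The 5 tested marrow precursor genes had a median of 3.26, as cells from bone marrow could give. None was called over all genes, and 2 passed when adjusted over the list alone (Ms4a3 at 1.79 and 24.0 with q = 0.138, Ctsg at 1.80 and 17.2 with q = 0.357). Prtn3 shares its position with Elane, and Igll1, not tested, was at 0.42 and 0.33 in the authors' deposited table. A sort on Sdc4 is meant to remove cells without it, but its purity was not assessed here. The erythroid marker Hba-a2 was at 430 and 496 and S100a8 at 426 in q1, so the sort alone cannot exclude such cells. Sample, handling and genotype stay untested.

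Cartilage genes were lower in q2 in part. Of 13 tested genes on a list added after the calls were seen, 4 fell: Col2a1, Col11a1, Acan and Clec3a. When adjusted over the list alone, 5 were lower and 0 higher, but the 4 called genes, known when the list was drawn, ease that adjustment. Of the 9 not called, 2 lay below 0 and 7 above, so a fall of the list beyond its called genes is not shown. Cartilage cells among the q1 cells would lower the other members too, but the 9 not called had a median of 0.36, at the 88.8th percentile of random lists, and all 13 together had 0.06 with Acan and Clec3a, listed at 0 in q2, ranked lowest, or 0.26 without them. Since 5 of those 9 were below 1 FPKM in q1 and leaving out called genes weakens the test, a few cartilage cells in q1 cannot be told apart from other sources. No biological explanation was tested.

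Calls at an exact 0 were frequent. Of all 79 tested genes with 1 side at 0, 18 were called. Of the 40 with the other side between 0.447 and 1.91 FPKM, 18 were called, or 45%. The share was 2.27%, or 1 of 44, among genes in that range above 0 on both sides and at least 16-fold apart (p = 1.98e-06, Fisher's exact test). That range was set by the lowest and highest values of the 18 calls, so it kept every one of them. Only uncalled genes with a side at 0 fell outside it, so neither the 45% nor the p-value can be taken at face value. All 18 had the smallest p in the authors' deposited table, 5e-05, and the lowest p of the uncalled genes with 1 side at 0 was 0.0281. The way the authors' test treats a group value of exactly 0 may account for part of these calls, Ifng, Il17a and Acan included, which these shares cannot decide. A truly larger difference in these genes would give the same shares and stays open.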
